A study of Homo sapiens with 18 samples.

How the data were processed

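Total RNA from 3 human ovarian cancer cell lines was sequenced in 18 libraries. The lines, as labelled, were OVCA429 (called WT below), an ARID1A knockout derived from OVCA429 (KO) and TOV21G, which carries an ARID1A mutation per the labels. Each line received the PBS carrier, interferon gamma for 2 h or interferon gamma for 8 h, which gives 9 groups of 2 libraries. Per the labels, ribosomal RNA was removed with a Ribo-Zero kit, and paired-end reads of 50 bases were aligned to GRCh38. The submitters' processing notes name STAR, HISAT2 and StringTie, with no version and no statement of which tool did what.

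The deposited table holds 1 value per gene and library in FPKM (fragments per kilobase of transcript per 1000000 fragments). Its header does not name the unit, and FPKM was judged from the values. The smallest values of genes with a single annotated transcript, multiplied by gene length, fell on a step that corresponds to 1 fragment. That step implied 61400000 to 97100000 fragments per library. At this depth 3 fragments in a gene of 1 kb give 0.0309 to 0.0488 FPKM, a floor that covers counting error only. The summed FPKM differed between libraries, from 648229 to 742668 once the small RNA RNU5D-2P was left out. The values were therefore not set to a common sum of FPKM, which is separate from the division by fragments that the unit holds. RNU5D-2P alone reached 9950000 FPKM in 1 library. Of 60468 genes in the table, 56746 (93.8%) matched an identifier of GENCODE release 29, and 19996 were listed at 0 in every library. A listed 0 can also be an estimate that failed, so single genes at 0 were not interpreted.

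Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 libraries were tested, which left 15965. A single linear model with 9 group means was fitted to all 18 libraries with limma 3.58.1 (limma-trend, not robust) in R 4.3.3, with 9 residual degrees of freedom and 2 prior degrees of freedom. Tests were two-sided and adjusted p values follow Benjamini and Hochberg over all genes tested in a contrast. A gene was called changed at an adjusted p below 0.05, with no limit on fold. The contrasts were the 2 h and 8 h responses of each line, KO against WT in each of the 3 conditions, the differences of response between lines, and the mean 8 h response of WT and KO. The model, the filter, the contrasts, the gene lists, the rule for naming genes and the main alternatives were chosen before the data were examined. TOV21G against WT in PBS was added after the data were seen, as was the restriction to protein-coding genes.

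For gene groups, 31 lists were fixed, of which 27 had at least 3 tested members and were compared with all other genes by camera with a preset correlation of 0.01. The same test with a correlation estimated from the data, and fry, were run as alternatives. Adjusted p values for lists cover the 27 lists within a contrast. For each list the number of called members is also given adjusted over the list alone. Genes named in the text came from 3 sources. These were 14 key genes of the interferon pathway and chromatin, the 10 largest called changes in each direction that moved the same way in every library pair with a mean of at least 5 FPKM, and up to 4 members of each list with the smallest p. Any gene outside this rule is marked as chosen after its values were seen. Of the key genes, the chemokine genes CXCL9, CXCL10 and CXCL11 did not pass the filter and were not tested, and the Th1 chemokine list had 0 tested members.

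The procedure was tested on simulated data with the same groups and libraries. Changed genes were drawn only from genes with a mean log2(FPKM + 1) above that of 5 FPKM. The noise was independent between libraries and genes, with the same spread in every group. Real libraries may not behave so, and genes at lower levels were not among those changed, so the numbers below may be too favourable for these data. Of 50 genes given a log2 change of 1, 48 were recovered in a simple response and 46 in a difference of responses. For a log2 change of 0.5 these numbers were 41 and 27. False calls were 15 of 203 in that response and 9 of 181 in that difference. Of 2 comparisons simulated with no change each gave 0 calls.

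Replicate numbers were not used as pairs. Over 36 pairs of groups the correlation of replicate differences ranged from -0.18 to 0.23, with 11 pairs above 0.1 and 2 below -0.1. A weak effect of the replicate number shared by some groups was therefore not excluded. The labels do not say whether the replicates were separate cultures, so the p values measure only the spread between these libraries, which may be technical. Within groups, the SD of the log2 difference between replicates was 0.496 to 0.576 over genes with a mean of at least 5 FPKM.

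Alternatives were median-of-ratios scaling, no filter, a filter of 5 FPKM in 2 libraries, a pseudocount of 0.1, the robust variant of limma-trend, the replicate number as a block, a fit of only the lines compared, a minimum log2 change of 1, and each library left out in turn. Where leaving out a library left 1 library in a group, that library was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9. Reads were not used here, so splicing, alleles and variants were not examined.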

Results

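The data are gene-level FPKM values from ribosomal RNA-depleted total RNA of 3 ovarian cancer cell lines. OVCA429 (WT) comes with a derivative labelled as its ARID1A knockout (KO), while TOV21G is a separate line labelled as ARID1A mutant. ARID1A encodes a subunit of the SWI/SNF chromatin remodelling complex. Each line was sampled after PBS, after 2 h and after 8 h of interferon gamma, with 2 libraries per group and 18 in all. The values implied 61400000 to 97100000 fragments per library, and 12966 to 13352 genes reached 1 FPKM. The comparisons address how each line responded to interferon gamma, and whether the response of KO differed from that of WT, with both names as the labels give them.

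After 2 h of interferon gamma, WT cells raised interferon target genes. IRF1 (ENSG00000125347, chromosome 5, 132481609 to 132490798), an early interferon-induced transcription factor, rose from 17.8 ± 0.525 to 430 ± 5.99 FPKM (SD, n = 2; log2 change 4.52, SE 0.101, adjusted p = 7.07e-10). GBP1, a GTPase of cell-autonomous immunity, rose by 3 on the log2 scale, and ICAM1, an adhesion molecule, by 2.82. IRF9, IRF8 and NLRC5, 3 further regulators of interferon-responsive transcription, rose by 2.03, 1.99 and 1.57, and the feedback inhibitor SOCS3 by 1.88. The metal-binding metallothionein gene MT1X rose by 2.21, and the stress-induced DDIT3 fell by 0.46. For each gene named here both treated libraries lay on the same side of both PBS libraries.

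Among the lists, 8 of 14 tested receptor and JAK-STAT genes rose in WT at 2 h (adjusted p = 1.27e-14), as did 11 of 16 interferon-induced transcription factors. Of 48 antiviral interferon-stimulated genes 12 rose, or 17 adjusted over the list alone. Of 21 MHC class I genes 4 rose, or 7 adjusted over the list alone, among them TAP1, the peptide transporter (log2 change 1.19). Of 13 mitochondrial mRNAs 10 rose, with a median log2 change of 0.58. In total 238 genes were called, 204 higher and 34 lower. The count was 121 to 154 with any 1 of the 4 libraries left out, and 33 in a fit of WT and no other line.

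Antigen presentation genes were among those raised in WT at 8 h. GBP1 (ENSG00000117228) rose from 3.89 ± 0.781 to 152 ± 21 FPKM (SD, n = 2; log2 change 4.97, SE 0.118, adjusted p = 2.84e-10), and the related GBP4 from 2.24 to 99.8 FPKM. CIITA, the master regulator of MHC class II genes, went from 0.131 to 9.65 FPKM (log2 change 3.23). WARS, a tryptophan tRNA ligase that interferon induces, reached 664 FPKM, and IDO1, a tryptophan-degrading enzyme, reached 6.1 FPKM from 0.0347. All 8 tested MHC class II genes rose, as did 18 of 21 MHC class I genes, 43 of 48 antiviral genes (45 adjusted over the list alone, adjusted p = 8.6e-72) and 8 of 9 guanylate-binding and related GTPases. Of 10 tested checkpoint ligands and IDO genes 7 rose, among them PDCD1LG2, which encodes PD-L2 (log2 change 2.77). CD274, which encodes PD-L1, stood at 24.4 ± 1.6 FPKM in PBS and 24.2 ± 2.42 at 8 h and was not called.

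Genes outside the interferon lists also moved in WT at 8 h. CTGF, a matricellular gene, fell by 1.48 on the log2 scale, SDPR, a component of caveolae, by 1.36, and the decoy death receptor gene TNFRSF10D by 1.07. CCND2, which encodes cyclin D2, fell by 0.84 and the signalling inhibitor SOCS2 by 0.93. Of 21 cholesterol synthesis genes 3 fell (adjusted p = 0.00482, and adjusted p = 0.106 with an estimated correlation). In total 1308 genes were called, 707 higher and 601 lower. The share called higher went from 54.1% to 65.6% with median-of-ratios scaling. The count was 679 without PBS replicate 1, 757 without PBS replicate 2, and 326 in a fit of WT and no other line. The lists of SWI/SNF and PRC2 subunits had adjusted p = 0.218 and 0.556.

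**Figure D1:**
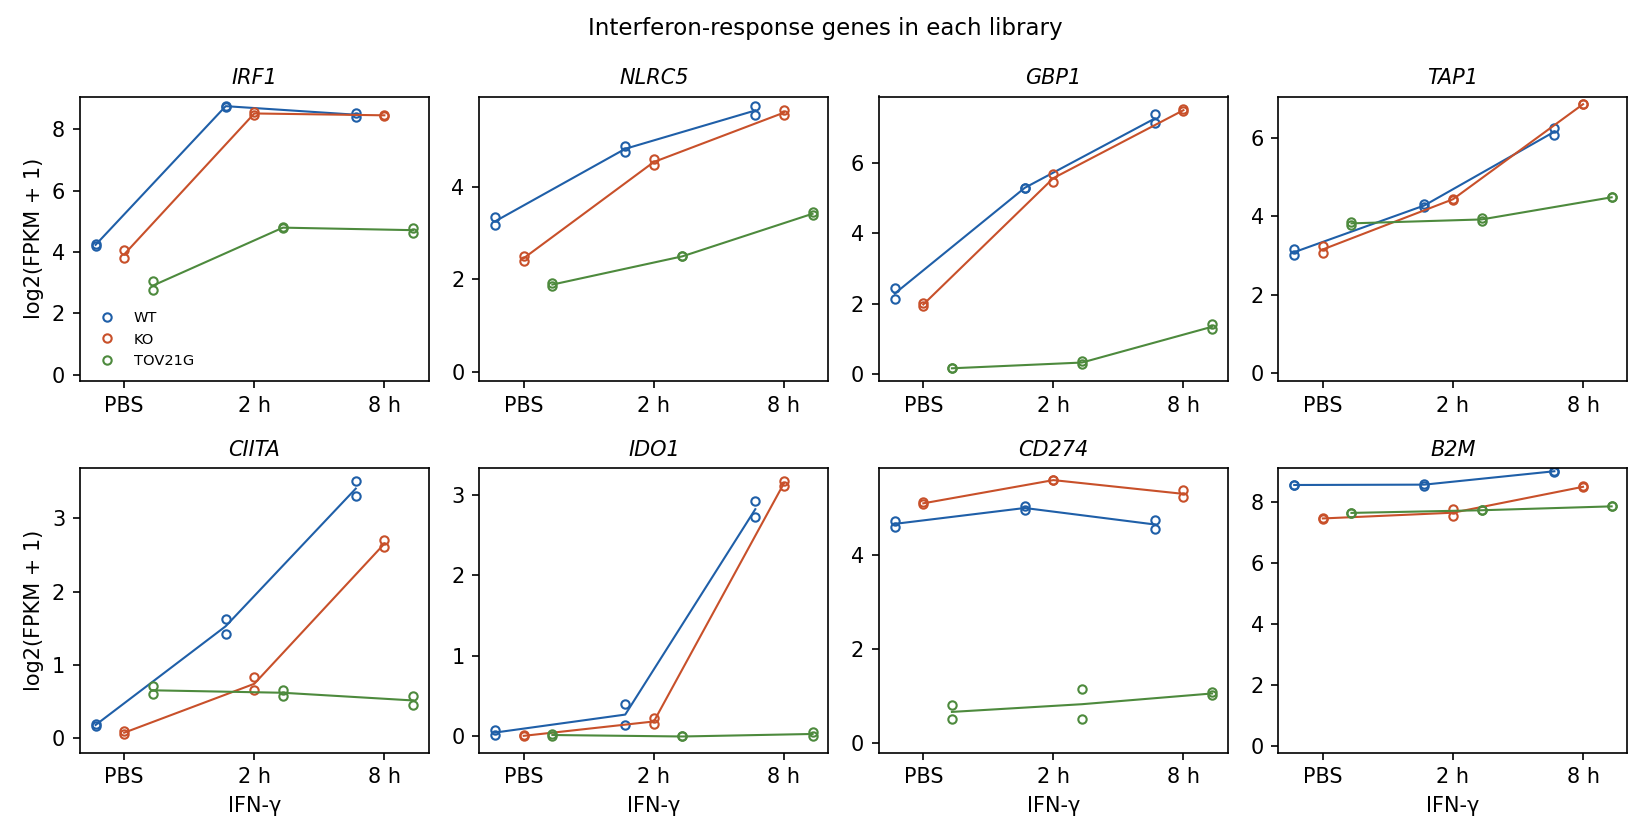
Each point is 1 library, the y axis is log2(FPKM + 1), the x axis is the condition, and lines join the means of the 2 libraries of a group, coloured by line. IRF1 reached 430 FPKM in WT and 365 in KO at 2 h, against 26.8 in TOV21G.

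In KO cells at 2 h IRF1 went from 14.2 to 365 FPKM (log2 change 4.59, SE 0.101, adjusted p = 5.96e-10), GBP1 rose by 3.59 and ICAM1 by 3.26 on the log2 scale. NLRC5, an activator of MHC class I genes, rose by 2.08 and the apolipoprotein L gene APOL6 by 1.91. HIST1H1D, a linker histone gene, fell by 0.66. Of 16 replication-dependent histone genes 6 fell (adjusted p = 0.128 with an estimated correlation). Of the 48 antiviral genes 13 rose, or 28 adjusted over the list alone, and 10 of 16 interferon-induced transcription factors rose. In total 357 genes were called, 188 higher and 169 lower. The count was 150 without PBS replicate 1, 159 without PBS replicate 2, 141 without 2 h replicate 2 and 1357 without 2 h replicate 1, and 72 in a fit of KO and no other line. WT and KO shared 109 called higher genes at 2 h, against 2.4 if the calls were independent. They were not, since both responses used the same variance estimate of each gene. Across all genes tested the 2 h log2 changes of WT and KO had a correlation of 0.01. Most of those genes were called in neither line, so this value says little about the genes that responded. Of 42 genes called higher in WT with a log2 change of 1 or more, 36 were also called higher in KO.

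In KO at 8 h GBP4 rose from 0.881 to 99.6 FPKM (log2 change 5.74, SE 0.093, adjusted p = 1.17e-11), GBP1 by 5.52, IDO1 by 3.14 and CIITA by 2.58 on the log2 scale. TAP1 went from 7.9 to 114 FPKM and the antiviral gene IFIT3 from 4.81 to 83.2. MHC class I genes rose in 18 of 21 cases with a median log2 change of 1.19, MHC class II genes in 7 of 8, and antiviral genes in 44 of 48. S1PR1, a lipid receptor gene, fell by 1.4, as did NOG, which encodes a BMP antagonist, while ID2 fell by 1.32 and SMAD6, a BMP pathway inhibitor, by 1.26. CTGF fell by 1.3. Of 27 SWI/SNF subunit genes 5 fell (adjusted p = 0.0678 with an estimated correlation), among them the ATPase gene SMARCA4 by 0.42. CD274 was not called, at 33.4 FPKM in PBS and 38.6 at 8 h. In total 1528 genes were called, 933 higher and 595 lower, 828 to 964 with any 1 of the 4 libraries left out, and 578 in a fit of KO and no other line. WT and KO shared 518 genes called higher, against 41.3 for independent calls, and 229 called lower, against 22.4. As at 2 h, the calls were not independent, and the log2 changes across all genes tested had a correlation of 0.31. Of 162 genes called higher in WT with a log2 change of 1 or more, 150 were also called higher in KO.

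TOV21G responded to a smaller extent. At 8 h IRF1 rose from 6.54 ± 1.08 to 25.3 ± 2.05 FPKM (SD, n = 2; log2 change 1.81, SE 0.101, adjusted p = 1.05e-05), NLRC5 by 1.53 and IRF9 by 1.22 on the log2 scale. TAP1 went from 13.1 to 21.3 FPKM. MT1E, a metal-binding metallothionein gene, rose by 2. NR4A1, an immediate-early nuclear receptor gene, fell by 1.31, and NEDD9, an adhesion scaffold gene, by 0.61. Of 48 antiviral genes 8 rose, or 18 adjusted over the list alone (adjusted p = 7.62e-09, and adjusted p = 0.0158 with an estimated correlation). Of 16 interferon-induced transcription factors 7 rose, and 5 of 21 MHC class I genes, or 11 adjusted over the list alone (adjusted p = 0.0775 with an estimated correlation). The MHC class II list had adjusted p = 0.736, with no gene of 8 called and 1 that rose when adjusted over the list alone. CIITA was not called and stood at 0.572 FPKM in PBS and 0.428 at 8 h.

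In TOV21G at 2 h IRF1 rose from 6.54 to 26.8 FPKM (log2 change 1.89, adjusted p = 6.08e-06) and SLC30A1, a zinc exporter gene, by 1.12 on the log2 scale. CXCL2 and CCL2, both chemokine genes, rose by 0.58 and 0.49. Both calls were lost with any 1 of the 4 libraries left out (adjusted p = 0.0845 to 0.184 for CXCL2 and 0.0837 to 0.184 for CCL2). Of 15 genes in their list 2 rose, or 7 adjusted over the list alone (adjusted p = 0.0176 with an estimated correlation). There were 53 calls at 2 h, 8 to 23 with any 1 of the 4 libraries left out, and 249 at 8 h, 45 to 94 with any 1 left out. In fits of TOV21G alone the counts were 9 and 14, and IRF1 had adjusted p = 0.0822 at 2 h and 0.0698 at 8 h. With scaling, 84 genes were called higher and 96 lower at 8 h, against 169 and 80 without it.

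KO and WT differed in many genes before any interferon. CALB2, which encodes the calcium-binding protein calretinin, stood at 45.3 ± 2.09 FPKM in KO and 0.776 ± 0.00242 in WT (SD, n = 2; log2 difference 4.7, SE 0.103, adjusted p = 2.23e-10). DIO2, a thyroid hormone-activating enzyme, and the pregnancy-specific glycoproteins PSG1 and PSG5 were higher by 4.39, 3.45 and 3 on the log2 scale. S100A14, a calcium-binding protein gene, was at 2.54 FPKM in KO and 40.1 in WT, and CCND2 at 2.52 and 35.6. The cytokine gene IL11 and the matrix gene TNC were also lower in KO. ARID1A itself (ENSG00000117713, chromosome 1, 26693236 to 26782110) was not called lower in KO in any of the 3 conditions. In PBS it stood at 6.27 ± 0.126 FPKM in KO and 4.55 ± 0.438 in WT (log2 difference 0.39, adjusted p = 0.0065). Without WT PBS replicate 2 the difference was 0.31 (adjusted p = 0.063). At 2 h and 8 h the difference was -0.04 and 0.15 (adjusted p = 0.752 and 0.268). ARID1A then stood at 5.086 and 4.453 FPKM in KO and at 5.263 and 3.925 in WT. In TOV21G it stood at 2.051 FPKM in PBS.

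Single interferon and antigen-presentation genes stood lower in KO than in WT in PBS, while their lists were not past the threshold with an estimated correlation. Of 48 antiviral genes 21 were lower and 0 higher, or 17 and 0 with scaling (adjusted p = 6.65e-05, and adjusted p = 0.0576 with an estimated correlation). Of 21 MHC class I genes 11 were lower and 2 higher, or 10 and 3 with scaling (adjusted p = 0.573 with an estimated correlation). HLA-B was lower by a log2 difference of -1.19 and B2M, the MHC class I light chain, went from 377 FPKM in WT to 176 in KO. NLRC5 differed by -0.8, IRF8 by -1.73 and MX2, an antiviral GTPase gene, by -1.3. Of 21 cholesterol synthesis genes 16 were lower and 1 higher (adjusted p = 5.31e-07, and adjusted p = 0.0576 with an estimated correlation), among them INSIG1 at -1.18 and HMGCS1 at -0.76. Of 16 mesenchymal genes 9 were lower and 3 higher (adjusted p = 0.573 with an estimated correlation), with FN1 at -1.65 and VIM at -0.86, while the laminin gene LAMA3 was higher by 0.95. EZH2, the PRC2 methyltransferase gene, was lower by a log2 difference of -0.41, JARID2 of the same complex higher by 0.71, and SMARCD3, another SWI/SNF subunit gene, differed by -1.31.

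In PBS 4260 genes were called between KO and WT, 1624 higher and 2636 lower in KO, and 2073 and 2094 with scaling, so the balance of directions depends on scaling. At 2 h there were 5458 calls and at 8 h 3687. In all 3 conditions 817 genes were higher and 1361 lower in KO. At 8 h HLA-B and B2M still differed by -0.63 and -0.51, CIITA by -0.75 and MX2 by -1.31, while TAP1 was higher in KO by 0.7, HLA-E by 0.78 and the transcription factor gene ETV7 by 1.1. MHC class I genes were then split, with 5 higher and 5 lower (adjusted p = 0.739). A single KO line against WT does not separate the knockout from other differences between the 2 lines.

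**Figure D2:**
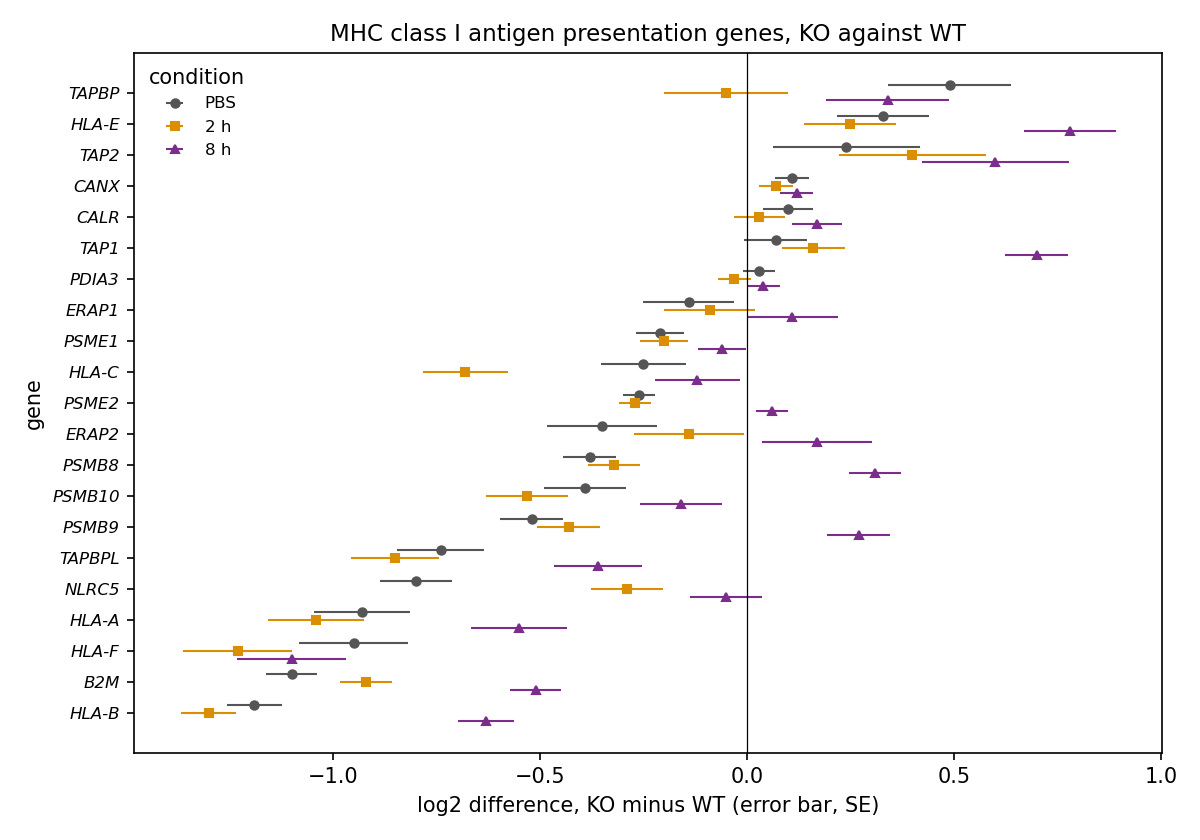
Points are log2 differences, KO minus WT, of the 21 tested MHC class I antigen presentation genes in PBS, at 2 h and at 8 h, and bars are 1 SE. In PBS 11 genes were lower in KO, and at 8 h 5 were lower and 5 higher.

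The difference between the KO and WT responses was tested directly. At 8 h APOL3, an interferon-inducible apolipoprotein L gene, had a larger response in KO by 1.2 on the log2 scale (SE 0.092, adjusted p = 9.63e-05), and APOL6 by 0.73 (adjusted p = 0.0014). APOL3 started lower in KO, at 3.69 against 9.28 FPKM, and reached 71.8 against 68.3. PSMB8 and PSMB9, the immunoproteasome subunit genes, had larger responses by 0.69 and 0.79 (adjusted p = 0.00791 and 0.0108). Without KO 8 h replicate 1 these values were 0.0541 and 0.0737. For PSMB9 the adjusted p was 0.0573 without KO PBS replicate 1 and 0.05 without KO 8 h replicate 2. Of 21 MHC class I genes 7 had a larger response in KO, or 9 adjusted over the list alone, and the median difference was 0.37 (adjusted p = 9.89e-10, and adjusted p = 0.08 with an estimated correlation). Differences of IRF1, CIITA, IDO1 and CD274 were not called (adjusted p = 0.505, 0.111, 0.345 and 0.822).

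The 13 mitochondrial mRNAs went the other way. MT-CO3 and MT-CO2, which encode respiratory chain subunits, rose by 0.3 and 0.39 in WT at 8 h and fell by 0.6 and 0.62 in KO, a difference of -0.9 and -1.01. Of the 13 mRNAs 7 had a lower response in KO, or 12 adjusted over the list alone, and the median difference was -0.82 (adjusted p = 2.65e-30, and adjusted p = 0.0194 with an estimated correlation). In total 54 genes were called at 8 h, 33 with a KO minus WT difference above 0 and 21 with one below 0, and with scaling 20 and 29. The count was 33, 28, 25, 30, 22 and 21 without WT PBS replicate 1 or 2, KO PBS replicate 1 or 2, and KO 8 h replicate 1 or 2. At 2 h 30 genes were called, among them the histone gene HIST1H3I at -0.86 and the protease gene RHBDD1 at 0.73. Without KO 2 h replicate 1 there were 993, and without any other single library 14 to 25.

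To compare the size of the response without favouring a line, 171 genes were taken that rose by at least 1 on the log2 scale in the mean of both lines. The median response was 1.47 in WT and 1.58 in KO, and 128 of the 171 had the larger response in KO, with 16 called larger and 4 called smaller. The count called larger was 4 and 5 without KO 8 h replicate 1 or 2, 7 without either KO PBS library, 8 and 10 without WT PBS replicate 2 or WT 8 h replicate 1, 9 with the replicate number as a block and 7 in a fit of WT and KO alone. The count called smaller was 1 with the block and 1 without WT PBS replicate 1, KO PBS replicate 1 or KO 8 h replicate 2, and 2 without KO PBS replicate 2 or KO 8 h replicate 1. The median difference was 0.19 (camera p = 2.08e-08, or 0.00363 with an estimated correlation). Without WT 8 h replicate 1 the mean difference was -0.04 and the p with an estimated correlation 0.0671. In PBS 68 of the 171 were lower and 8 higher in KO, with a median difference of -0.19, and at 8 h 45 were lower and 34 higher, with a median of -0.03. Some of the 171 called larger or smaller were non-coding loci with a change of 0 in 1 of the 2 lines. With protein-coding genes alone, 112 of 143 had the larger response in KO, with 15 called larger and 2 smaller. A planned set from other libraries held 12 genes called in TOV21G at 8 h with a log2 change of 1 or more. Of these 7 had the larger response in KO and 3 the smaller (camera p = 0.0262, or 0.0585 with an estimated correlation).

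**Figure D3:**
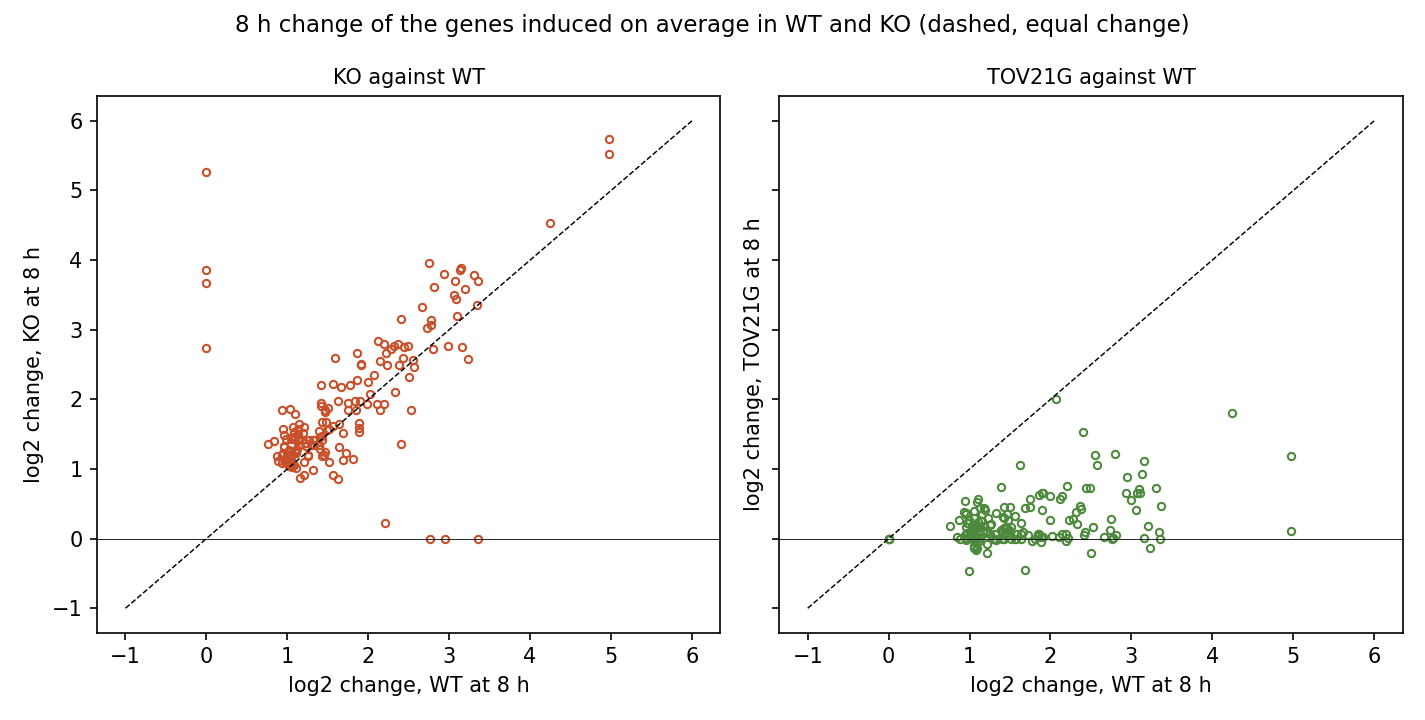
Each point is 1 of the 171 genes induced on average in WT and KO, with its 8 h log2 change in WT on the x axis and in KO (left) or TOV21G (right) on the y axis, and the dashed line marks equal change. In KO 128 genes lie above the line.

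The 8 h responses of GBP4, GBP1, CIITA and IDO1 were smaller in TOV21G, by log2 differences of -4.86, -3.79, -3.37 and -2.76 (GBP4 SE 0.132, adjusted p = 2.87e-09). For IRF1 the difference was -2.43, and for JAK2, the receptor-associated kinase gene, -1.29. To favour neither line, 66 genes were taken that rose by at least 1 on the log2 scale in the mean of both, a set added after the data were seen. The median response was 2.5 in WT and 0.47 in TOV21G, and 59 were called smaller in TOV21G. A short Y RNA, chosen after its values were seen, was the 1 called larger. With any 1 of the 8 libraries left out, 58 to 66 were called smaller and 0 to 3 larger. Of the 66 genes 26 stayed below 1 FPKM in every TOV21G library. MHC class II genes differed by a median of -1.42, guanylate-binding and related GTPases by -1.57 and antiviral genes by -0.9. SDPR and CTGF, which fell in WT, differed by 1.38 and 1.36. In total 858 genes were called, 430 higher and 428 lower, and with scaling 222 and 519. The count was 481 without WT PBS replicate 2, 1378 without WT 8 h replicate 2, 512 without TOV21G PBS replicate 2 and 442 without TOV21G 8 h replicate 1.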

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

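The tests of mitochondrial mRNAs below were chosen after the result was seen, while the tests of differences between lines were planned. The values in this part differ between lines by a test of the difference itself. The number of such genes was 30 for KO minus WT at 2 h, 54 for KO minus WT at 8 h and 858 for TOV21G minus WT at 8 h.

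For KO minus WT at 8 h, the median log2 difference was 0.37 for MHC class I genes, -0.23 for MHC class II genes, 0.19 for checkpoint ligands and IDO, 0.18 for antiviral genes, 0.22 for cell death genes, 0.28 for cholesterol synthesis and -0.82 for mitochondrial mRNAs. With an estimated correlation the first 4 of these had adjusted p = 0.08, 0.314, 0.177 and 0.0844, and the cell death, cholesterol and mitochondrial lists stayed below 0.05 (adjusted p = 0.0148, 0.0148 and 0.0194). At 2 h it was -0.28 for histones and -0.68 for mitochondrial mRNAs (adjusted p = 0.868 and 0.659 with an estimated correlation). Single genes at 8 h were APOL3 at 1.2, APOL6 at 0.73, ETV7 at 0.87, ICAM1 at 0.8, PSMB9 at 0.79, NLRC5 at 0.75, PSMB8 at 0.69, B2M at 0.59, HIST1H3I at -0.64, MT-CO3 at -0.9, MT-ND3 at -0.99 and MT-CO2 at -1.01. At 2 h they were RHBDD1 at 0.73, APOL6 at 0.49, ID1 at -1.12, HIST1H3I at -0.86 and S1PR1 at -0.83. Without KO 8 h replicate 1 the adjusted p of ETV7, ICAM1, NLRC5 and B2M rose to 0.0794, 0.142, 0.159 and 0.116, and without WT 2 h replicate 2 that of APOL6, ID1 and S1PR1 at 2 h to 0.165, 0.151 and 0.0826. HIST1H3I at 8 h had adjusted p = 0.0556 without KO PBS replicate 1 and 0.0614 without KO 8 h replicate 1. At 2 h the calls of APOL6, ID1 and S1PR1 were also lost without several other single libraries.

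For TOV21G minus WT at 8 h, the median was -0.85 for receptor and JAK-STAT genes, -0.39 for other chemokines, -0.68 for MHC class I, -1.42 for MHC class II, -1.18 for checkpoint ligands and IDO, -1.57 for guanylate-binding and related GTPases and -0.9 for antiviral genes. It was -1.25 for interferon-induced transcription factors, -0.57 for cell death genes, -0.9 for complement, -0.52 for NF-kB targets, 0.29 for MYC targets, 0.23 for the unfolded protein and integrated stress response, -0.39 for immediate-early genes, -0.1 for clear cell markers and -0.45 for mitochondrial mRNAs. With an estimated correlation the stress, immediate-early, clear cell and mitochondrial lists had adjusted p = 0.123, 0.114, 0.11 and 0.0589. Single genes were GBP4 at -4.86, GBP1 at -3.79, CIITA at -3.37, WARS at -2.89, IDO1, ICAM1 and PDCD1LG2 at -2.76 each, IRF1 at -2.43, MT1X at -1.35, JAK2 at -1.29 and MT2A at -1.23, with SDPR at 1.38, CTGF at 1.36, SOCS2 at 1.21 and TNFRSF10D at 1.12.

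Mitochondrial mRNAs rose in WT and fell in KO after interferon. Their summed FPKM went from 4376 and 4828 to 5899 and 5959 in WT at 8 h, and from 6232 and 5660 to 4233 and 4546 in KO. The tables argue against scaling between libraries, since the median difference was -0.87 after median-of-ratios scaling, and against a single library, since it was at most -0.67 with any 1 of the 8 libraries left out. A change of the whole respiratory chain is argued against by 77 nuclear genes of that chain, with a median of 0.15, quartiles of 0.05 and 0.21 and 0 calls by limma. What stays open is a different yield of mitochondrial RNA between cultures or extractions, and a change of mitochondrial transcription that may differ between the lines, and neither was tested.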

How the results depend on the processing

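The restriction to protein-coding genes and the contrast of TOV21G with WT in PBS were chosen after seeing the data, and the other alternatives before. Requiring a log2 change of 1 left 43, 172, 47, 211, 6 and 18 genes for the WT, KO and TOV21G responses (2 h, then 8 h in each), 373, 373 and 336 for KO against WT in PBS, at 2 h and at 8 h, 8 and 12 for the KO minus WT differences, 142 for TOV21G minus WT and 194 for the mean response. Fits of only the lines compared left 33, 326, 72, 578, 9 and 14 for the 6 responses, and 11 and 28 for the KO minus WT differences at 2 h and 8 h. In such fits the variance comes from fewer libraries and from those lines alone, and which of these lowered the counts was not tested. Without a filter TOV21G had 225 and 404 calls and the KO minus WT differences 64 and 90. With the replicate number as a block these counts were 28, 148, 18 and 32. The robust fit gave 165 for TOV21G at 8 h, and a pseudocount of 0.1 gave 28 for KO minus WT at 8 h. With libraries left out in turn the ranges were 121 to 154 (WT, 2 h), 679 to 1196 (WT, 8 h), 141 to 1357 (KO, 2 h), 828 to 964 (KO, 8 h), 8 to 23 and 45 to 94 (TOV21G), 14 to 993 and 21 to 57 (KO minus WT at 2 h and 8 h) and 442 to 1378 (TOV21G minus WT). For KO against WT they were 2921 to 3158, 3657 to 5416 and 2473 to 3581, for the mean response 1707 to 2378, and for the share of the induced genes with a larger KO response 65.6 to 77.6%. List calls went from 141 to 72 of 351 with an estimated correlation. GBP6 changed sign in the KO minus WT difference at 8 h with a pseudocount of 0.1 (0.238, adjusted p = 0.885). The extracellular matrix list at 2 h changed direction between KO and WT with fry (adjusted p = 0.00799). Except where the construction of the alternative shows it, the cause was not tested. Of 1828 results for single genes, 1089 were called in the main fit, and a result that was never called also counts below as kept. Of the 1828, 1773 kept their side of the threshold with scaling, 1736 without a filter and 1754 with a pseudocount of 0.1. The number was 1814 with the robust fit, 1756 with the block and 1565 in fits of only the lines compared. In the last of these 259 calls were lost and 4 gained. Depth limits single genes near the floor of 0.0309 to 0.0488 FPKM.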

Other observations

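The tests of explanations in this part, with the count of splits, and the comparison of TOV21G with WT in PBS were chosen after the result was seen. The responses, KO against WT and leaving out each library were planned. TOV21G and WT differed in PBS in most genes tested, with 11268 of 15965 called, 5578 higher and 5690 lower in TOV21G. Of these, 2029 and 2023 differed by at least 1 on the log2 scale. Some genes at the start of the interferon pathway were among them, so a difference in PBS is not particular to that pathway. JAK1, the kinase bound to the receptor and chosen after its values were seen, stood at 3.87 ± 0.279 FPKM in TOV21G and 44.4 ± 0.186 in WT (SD, n = 2; log2 difference -3.22, adjusted p = 2.56e-13). The receptor genes IFNGR1 and IFNGR2 were higher in TOV21G by 2.03 and 3.12 on the log2 scale, and IRF1 differed by -1.33. Whether the JAK1 level accounts for the smaller response was not tested.

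Tissue markers were also among the many genes that differed between these 2 lines. Of 8 clear cell carcinoma markers 6 were higher in TOV21G (adjusted p = 0.00114, and adjusted p = 0.0595 with an estimated correlation). SPP1, a secreted phosphoprotein gene, stood at 897 FPKM against 0.967, and FXYD2, a sodium pump regulator, at 413 against 0.538. Of 15 epithelial markers 14 were lower (adjusted p = 1.85e-07, and adjusted p = 0.105 with an estimated correlation), with the keratin gene KRT7 at 4.39 against 1400 FPKM and the cadherin gene CDH1 at 0.375 against 62.6.

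At 8 h MT1X, MT1E, MT1F, MT2A and the zinc exporter gene SLC30A1 rose in all 3 lines. They were no list of their own and were not tested as a group. Of 6 tested metallothionein genes 4 were called higher in WT, 4 in KO and 5 in TOV21G, the fifth being MT1A (adjusted p = 0.0422, and 0.0594 with scaling). In TOV21G only MT1E stayed called with any 1 of the 4 libraries left out, while the adjusted p reached 0.244 for MT1A, 0.0801 for MT1X, 0.224 for MT1F and 0.0988 for MT2A. MT1E rose by 2.07, 2.35 and 2 on the log2 scale in WT, KO and TOV21G, and SLC30A1 by 1.09, 1.44 and 0.52. Both were already called higher at 2 h in every line, MT1E by 1.38, 1.39 and 1.33 and SLC30A1 by 1.78, 2.43 and 1.12. MT1X, MT1F and MT2A were called higher at 2 h in WT and KO but not in TOV21G. In TOV21G at 8 h the SLC30A1 call was lost with any 1 of the 4 libraries left out (adjusted p = 0.0988 to 0.185). The metallothionein genes were chosen after their values were seen. Reads shared between paralogs, as the reason why several metallothionein genes rise, cannot be told apart. The summed FPKM of the 9 genes lay above PBS in both 8 h libraries in 3 of 3 lines, but 1 rising member would raise that sum too. The same path as the interferon list genes cannot be told apart. The median ratio of the TOV21G to the WT change was 0.47 over 5 metal genes against 0.17 over 57 interferon list genes, with an upper quartile of 0.29 and a highest value of 0.64 among the latter. All 5 metal genes lay above that quartile (lowest 0.35) and 2 above the highest value, MT1E at 0.97 and MT1F at 0.66. The 5 genes were picked because they rose in every line, which favours a high ratio, so these values decide nothing. A metal-responsive signal cannot be told apart either, since the importer gene SLC39A10 was called lower at 8 h in 2 lines of 3 (WT and KO). That call was lost in WT without PBS replicate 1 (adjusted p = 0.0752) or 8 h replicate 2 (0.0501), and in KO without PBS replicate 2 (0.0733) or 8 h replicate 1 (0.0637). Metal carried in the interferon preparation could not be separated, with no carrier control other than PBS.

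ARID1A was not called lower in KO than in WT, with log2 differences of 0.39 in PBS, -0.04 at 2 h and 0.15 at 8 h (adjusted p = 0.0065, 0.752 and 0.268). Without WT PBS replicate 2 the PBS value was 0.31 (adjusted p = 0.063). A single mislabelled library is argued against, since 12 of 12 WT and KO libraries correlated better across genes with their own line than with the other. WT and KO labels exchanged as a whole, and knockout transcripts that are not degraded, cannot be told apart, since reads over the edited site were not used here. If the labels were exchanged as a whole, every KO minus WT direction given here and above would turn. A knockout by small changes in the sequence may leave the RNA level as it was.

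For the mean 8 h response of WT and KO, 34 of the 35 splits of the 8 libraries could be fitted. Each fit held line and the split as separate terms, and the split that could not be fitted is that between the lines. The real split gave 2248 calls, the highest other fitted split 6, and 1 split, the real one, gave as many. Over all 35 splits the share is 0.0286 if the split that was not fitted is counted as smaller. It is 0.0571 if that split is counted as equally large. Treatment was given within each line, so only splits with equal numbers of each line on both sides match the real split. Those were not counted apart, and the shares above include uneven splits, so they decide nothing about whether chance could give as many calls.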
